A study of Bos taurus with 2 samples.

How the data were processed

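Small RNA was sequenced from 2 pooled liver libraries, 1 per RFI line, each made from RNA of 13 bulls with 1 ug of RNA from each animal, per the labels' protocols. The libraries were prepared with a small RNA kit protocol and read for 36 cycles on an Illumina Genome Analyzer IIx, per the labels' protocols. Bowtie is named in the submitters' processing notes, with no version and no role. A genome build is not given in the sources used here. The deposited values are raw counts of reads per distinct 35 nt tag, not normalized, with the 3 prime adapter still in the tags. The deposited files held no alignment and no gene names.

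The adapter ATCTCGTATGCCGTCTTCTGCTTG was removed at the leftmost place where its first 6 nt matched exactly and at most 20% of the rest mismatched. An insert of more than 29 nt leaves fewer than 6 nt of adapter in the tag, so such reads were counted as having no adapter. Shorter inserts with a read error in the first 6 nt of adapter also fall in this class, and the length of its inserts is unknown. Shares of insert lengths were taken over reads of 15 nt or longer, including those with no adapter. Total depth was 12196461 reads in low RFI and 14117842 in high RFI, which sets the width of the counting intervals.

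Naming miRNAs needs their sequences, which were not used here. The 18 lists of miRNAs, the share of one named miRNA, the share of reads in annotated miRNAs and the usage of hairpin arms, all planned before the data were examined, were therefore not computed. By the fallback planned for this case, tags were reported by sequence. The scheme that joined them was chosen after the data were examined. Inserts of 18 to 26 nt were taken in order of abundance over both libraries and joined to a more abundant sequence if the 5 prime end lay within 2 nt, the 3 prime end within 4 nt, and at most 2 untemplated A or T were added. Reads that matched several groups equally well were left out. Of 2399 groups with at least 100 reads, 1635 were set aside as fragments, because at least 20% of the reads with their 16 nt core were in tags with inserts of 27 nt or longer or no adapter. Another 295 were set aside as possible read errors, 1 substitution from a group at least 50 times as abundant. That factor was set after a lower one was seen to remove an abundant related sequence. Forms that lacked 1 base of a more abundant group were not screened. Some of them stayed among the groups counted, named and joined into families. The 469 groups left were the defined-length groups. CPM were computed over the reads in these groups, and log2 ratios with 0.5 reads added.

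The rule for named groups took the 10 highest mean CPM and the 10 highest and 10 lowest ratios, ranked by the bound of the 95% counting interval nearest to 1. After the data were examined, groups at least 32-fold different or with fewer than 10 reads in a library were taken out of the ranking as nearly confined to 1 library. The first form of this rule used the 32-fold limit alone. Their sequences are not reported, since their origin was not established. Members of the 6 most abundant families were also named, up to 4 of the highest mean CPM in each, a limit set after the data were examined. The forms with 1 substitution, the parent sequence of a family and the tags with no adapter were named after their values were seen.

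Shares have exact Clopper-Pearson intervals and ratios have exact conditional binomial intervals, which cover counting error only. A size of 1.5-fold was the fixed threshold, and no p-value was computed. Family medians were set against 10000 random lists of the same size matched on abundance, with percentiles under 2.5 or over 97.5 described as standing apart. The families, the relation with GC content, the removal of its trend by lowess with a span of 0.5, the scaling to the total of 18 to 26 nt inserts and the scan for substitutions were chosen after the data were examined. The median log2 ratio, 0.66, was added back when the trend was removed, so values with the GC trend removed keep the main scaling. Scalings by edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors, in R 4.3.3, were used as alternatives. Other alternatives were the definition of a group, the minimum of reads, the adapter length, the use of tags read once and the size threshold. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for figures.

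The counting of ratios was tested on simulated data with 469 groups at the depths of the low RFI and high RFI libraries. Groups simulated with a 2-fold change passed 1.5-fold in the right direction in 96.8% of cases, and with a 4-fold change in 100%. Groups simulated at 1.5-fold did so in 52.9%, and unchanged groups passed it in 1.49%. These figures include counting error and no variation between animals or preparations. The simulated tags held only the 469 sequences with fixed end forms and no read errors, so the figures do not cover how real tags were joined or set aside. The simulated ratios were centred by their known true values before the threshold was applied, which removed any error of scaling. The real ratios had no such correction, so the figures do not cover the choice of scaling.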

Results

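Small RNA from liver was compared between lines of Angus cattle bred in opposite directions for residual feed intake (RFI), the feed an animal eats beyond what its weight and growth predict. Animals with low RFI eat less than predicted. Liver biopsies came from bulls at 13 months of age. RNA of 13 bulls of the low RFI line was pooled in equal amounts into 1 library, and RNA of 13 bulls of the high RFI line into another. The low RFI library held 12196461 reads in 1091541 distinct tags, and the high RFI library held 14117842 reads in 1029557 distinct tags. Each line was thus measured in 1 library, with no replicate, so that the line, the library and its preparation cannot be separated and no test between the lines was made. The intervals given for shares are exact 95% Clopper-Pearson intervals, and those given for ratios are exact 95% conditional binomial intervals. They cover counting error of reads only. The reads carry no molecular identifiers, so copies of 1 molecule cannot be told from separate molecules, and the intervals may be too narrow for molecules. The intervals say nothing of the spread between animals, which were pooled.

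The first question was which kinds of small RNA each library held. Inserts of 18 to 26 nt made up 44.7% of the reads in low RFI and 50.1% in high RFI. Reads in which no adapter was found, whose insert length is unknown, made up 40.8% in low RFI and 30.9% in high RFI. Very short inserts of 1 to 14 nt were more frequent in high RFI, at 6.80% against 2.55%. So were inserts of 15 to 17 nt, at 3.86% against 1.69%. Among reads of 15 nt or longer, 22 nt was the most frequent insert length of those resolved in both libraries, with 15.3% of the reads in low RFI and 16.8% in high RFI. Over inserts of 18 to 26 nt alone the order turned, with 31.1% in low RFI and 29.7% in high RFI. The 20 nt class was 6.11% in low RFI and 13.1% in high RFI. Among inserts of 15 to 19 nt, the share that ended in CCA, the 3 prime end of mature transfer RNAs, was 2.81% (2.77 to 2.86) in low RFI and 4.89% (4.85 to 4.93) in high RFI. It was also lower in low RFI among inserts of 25 to 29 nt, at 1.46% against 2.19%, and slightly higher among those of 20 to 24 nt, at 1.16% (1.151 to 1.170) against 1.11% (1.106 to 1.122). In that class, 1 sequence supplied 26.9% of the reads ending in CCA in low RFI and 33.9% in high RFI. Other RNAs can end in CCA too, so these shares do not measure transfer RNA.

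**Figure D1:**
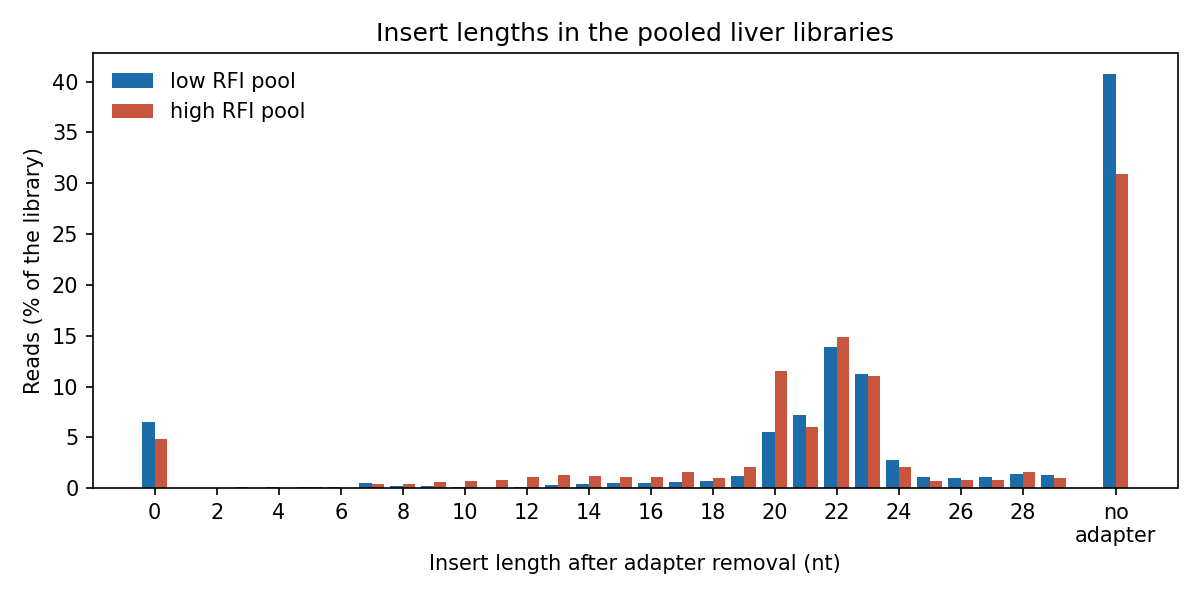
Insert lengths in both libraries. Bars give the reads of each insert length (nt) as a percentage of all reads of the library, blue for the low RFI pool and red for the high RFI pool; a length of 0 is adapter without insert (6.49% and 4.80%), and the bars at the right are reads with no adapter found (40.8% and 30.9%).

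The second question was which small RNAs of defined length were most abundant. Inserts of 18 to 26 nt that differed only at their ends were joined into sequence groups, each named by its most abundant sequence. No miRNA sequences or genome were used here, so groups are given without gene names or positions. There were 469 groups of defined length with at least 100 reads over both libraries. They held 39.0% of the reads of 15 nt or longer in low RFI and 47.6% in high RFI. The 10 most abundant groups held 69.0% of the grouped reads in low RFI and 78.2% in high RFI. The group of TGAGATGAAGCACTGTAGCT was the most abundant in both libraries and took 15.7% of the grouped reads in low RFI and 30.9% in high RFI, 1.96-fold more (1.96 to 1.97). Its log2 ratio, low RFI over high RFI, was -0.97, and it was -1.62 with TMM scaling.

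Among the other abundant groups, TACAGTACTGTGATAACTGAAG was 3.23-fold higher in high RFI (3.20 to 3.26), CTGACCTATGAATTGACAGC 2.13-fold higher (2.11 to 2.14) and TCAGTGCACTACAGAACTTTGT 1.56-fold higher (1.55 to 1.57). Their log2 ratios were -2.34, -1.74 and -1.29 with TMM scaling. TGTAAACATCCTCGACTGGAAGC, at 12.2% in low RFI and 14.1% in high RFI, had a log2 ratio of -0.21, which was -0.86 and past 1.5-fold with TMM scaling. In the opposite direction, TGGAGTGTGACAATGGTGTTT was 2.57-fold higher in low RFI (2.56 to 2.58), with 11.9% of the grouped reads against 4.62%, and stayed past 1.5-fold with TMM scaling, at a log2 ratio of 0.71. TGAGGTAGTAGGTTGTATAGTT was 2.08-fold higher in low RFI (2.06 to 2.09), and TACCACAGGGTAGAACCACGGA 1.68-fold higher (1.66 to 1.69). With TMM scaling their log2 ratios were 0.40 and 0.10, no longer past 1.5-fold. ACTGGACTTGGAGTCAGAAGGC had a log2 ratio of 0.62, which was -0.03 with TMM scaling. TGAGGTAGTAGATTGTATAGTT had 0.42, which was -0.23 with TMM scaling. Of the 10 groups, 5 were higher in low RFI as scaled here and 3 with TMM scaling. Removing the trend of the ratios with GC content also moved several of them. It took TCAGTGCACTACAGAACTTTGT to a log2 ratio of -0.16, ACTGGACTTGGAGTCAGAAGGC to 0.27 and TACCACAGGGTAGAACCACGGA to 0.39, none of them still past 1.5-fold, and TACAGTACTGTGATAACTGAAG from -1.69 to -0.80. It took TGAGGTAGTAGATTGTATAGTT to 1.70, past 1.5-fold in low RFI, and TGAGGTAGTAGGTTGTATAGTT from 1.05 to 1.94. This step kept the median log2 ratio of 0.66 over the groups not nearly confined to 1 library. Whether a value passed 1.5-fold with the GC trend removed thus depends on the scaling too.

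**Figure D2:**
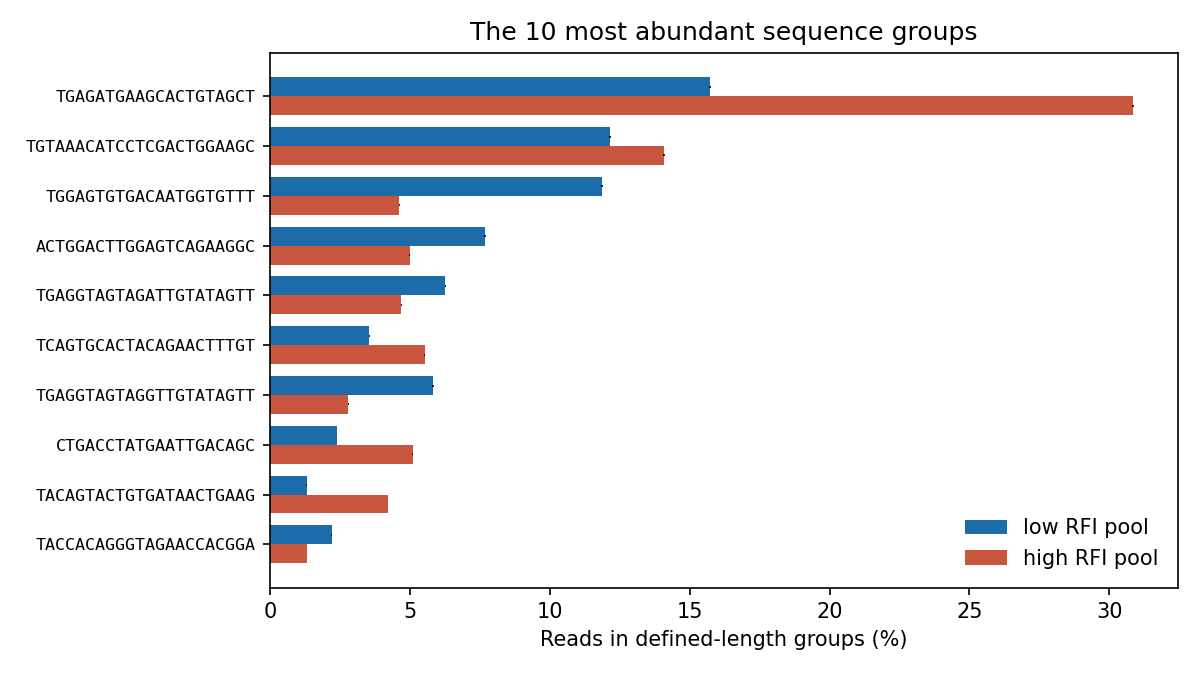
The 10 most abundant sequence groups. Bars give each group's reads as a percentage of the reads in defined-length groups, blue for the low RFI pool and red for the high RFI pool, with exact 95% counting intervals as error bars; TGAGATGAAGCACTGTAGCT reaches 15.7% in low RFI and 30.9% in high RFI.

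The third question was how many groups differed between the libraries by a fixed size. As scaled to the total of grouped reads, 254 of the 469 groups were at least 1.5-fold higher in low RFI and 100 were at least 1.5-fold lower, so 71.8% of those past the threshold were higher in low RFI. Without the groups nearly confined to 1 library, whose origin was not established, the numbers were 230 and 88. With the GC trend removed the numbers were 258 and 69, or 78.9% higher. With TMM scaling they were 134 and 138, or 49.3% higher. TMM scaling shifted every log2 ratio by -0.65, and the median over the groups went from 0.69 to 0.04. Under all of the scalings tried, 134 groups were higher and 100 lower by at least 1.5-fold. Each other scaling lowered every log2 ratio, so these equal the number higher with TMM scaling and the number lower as first scaled. The log2 ratio also moved with base composition. Across the 163 groups of at least 1000 reads that were not nearly confined to 1 library, it rose with GC content with a Pearson correlation of 0.38 and a Spearman correlation of 0.50. Groups are not independent replicates, and no p-value was computed. Over all 433 groups of at least 100 reads that were not nearly confined, the median log2 ratio was -0.87 in groups under 35% GC and 1.09 in groups of 60% GC or more.

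Of the 469 groups, 36 were nearly confined to 1 library, 24 to low RFI and 12 to high RFI. All of the 10 highest and all of the 10 lowest groups by the ranking were among these. Their origin was not established, so they are given as counts, and the next 10 in each direction are named. Highest in low RFI was GCAGTCCATGGGCATATACACC, 16.5-fold (14.99 to 18.1), with 5747 reads in low RFI and 479 in high RFI. Other well-counted groups were TGAGGGGCAGAGAGCGAGACTTT, 4.21-fold higher in low RFI (4.14 to 4.29), TTCACCACCTTCTCCACCCAGC, 4.19-fold (3.77 to 4.67), and TCAGTGCATCACAGAACTTTGT, 3.88-fold (3.76 to 4.01). The remaining groups named here as high in low RFI had at most 719 reads there, and were CTGCCAATTCCATAGGTCACAG, AGATGTACCGTGCGATTCAGACTGT, TCAATCCCCGGCATCTCCACCA, TTGGCTTGCACGAGGCCCCGGGT, GTAGAGGAGATGGCGCAGGGGACA and TGGTTTACCGTCCCACATACA, the last at 7.10-fold (4.51 to 11.6). All 10 stayed at least 1.5-fold higher in low RFI with TMM scaling and with the GC trend removed. The outcome with TMM scaling follows from their size, since it shifts every log2 ratio by -0.65. With identical inserts only, TTGGCTTGCACGAGGCCCCGGGT went from a log2 ratio of 2.42 to 3.92.

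In high RFI, AGAATCTAGATGAACTTTTTGG was 16.7-fold higher (10.8 to 27.2), with 481 reads against 21, and CAGGGAATTTAAATAGAACTTCAGC 15.3-fold higher (9.14 to 27.7). CTCCCGCCTTTTTTTTCTTG was 9.26-fold higher (8.37 to 10.3), with 5121 reads against 403, and CTCCCGCCTTTTTTTTTC, which shares its start, was 11.4-fold higher (8.36 to 15.8). GGCTCTGTGGCGCAATGGA was 8.40-fold higher (6.79 to 10.5), CATCTAGACTGTGAGCTTCTAG 6.68-fold (5.73 to 7.82) and GCCCCAGTTGCCTAATGGA 5.61-fold (4.59 to 6.93). The others were TTGATACTCTAGCCGAGAGA, TAGAACAGGGCTTAGTTA and AAAGACTCAAACGAACTTTTGG, with at most 37 reads in low RFI. The groups at 16.7, 8.40 and 5.61-fold and the last named each differed by 1 substitution from a more abundant group. Those more abundant groups were 1.62, 2.67, 4.49 and 2.42-fold higher in high RFI, in that order. The 10 groups were thus not all independent. With 1 mismatch allowed, the group at 5.61-fold went from a log2 ratio of -2.48 to -3.19. All 10 stayed at least 1.5-fold lower in low RFI with the GC trend removed, but their sizes and order moved. TMM scaling shifts every log2 ratio by -0.65, so it could only widen these differences and does not test them. With the GC trend removed, the log2 ratio of AGAATCTAGATGAACTTTTTGG went from -4.03 to -2.75, that of CAGGGAATTTAAATAGAACTTCAGC from -3.89 to -2.97, that of AAAGACTCAAACGAACTTTTGG from -2.69 to -1.80 and that of TAGAACAGGGCTTAGTTA from -2.84 to -2.18. With identical inserts only, CTCCCGCCTTTTTTTTCTTG went from -3.21 to -2.48, CTCCCGCCTTTTTTTTTC from -3.49 to -5.18, TTGATACTCTAGCCGAGAGA from -3.08 to -4.78 and TAGAACAGGGCTTAGTTA to -6.51.

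**Figure D3:**
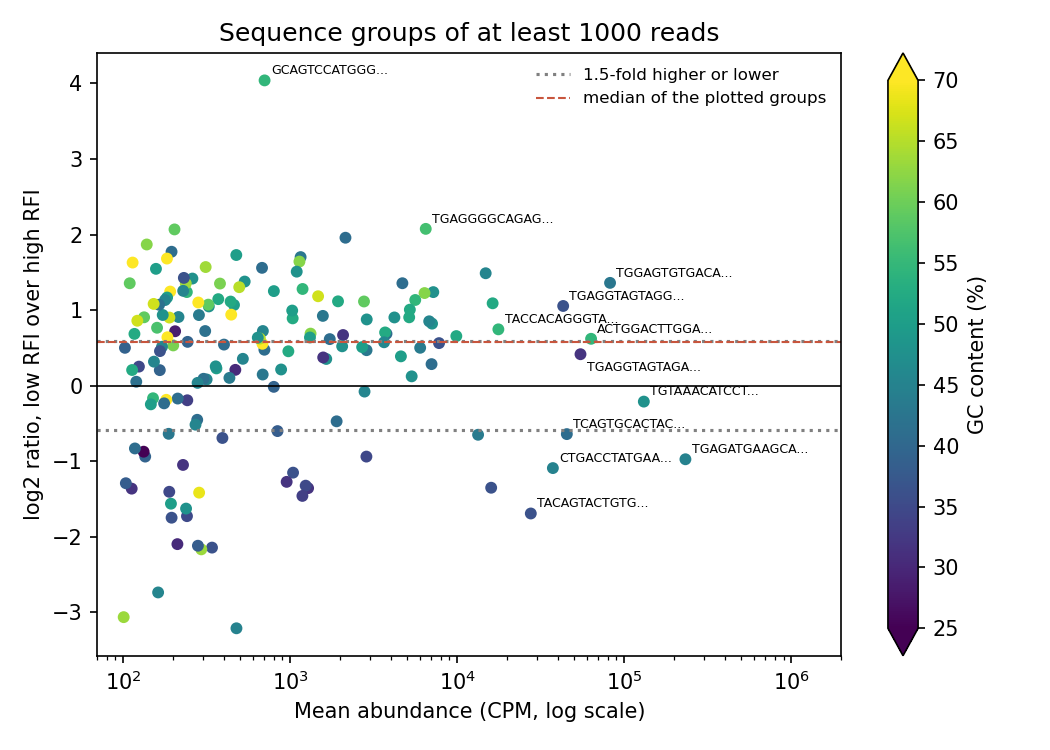
Log2 ratio, low RFI over high RFI, against mean abundance (CPM, log scale) for the 163 sequence groups of at least 1000 reads not nearly confined to 1 library, coloured by GC content. Dotted lines mark 1.5-fold and the dashed red line the median of 0.58, which lies on the upper dotted line; groups of low GC content lie mostly below it.

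Groups that share bases 2 to 8, the part of a miRNA that pairs with its targets, were joined into families, a grouping chosen after the data were examined. Some members lacked 1 base of a more abundant member, so members were not all independent. The log2 ratio was -1.15 in 1 such form of the most abundant group, against -0.97 in that group. It was 1.20 and 0.84 in 2 such forms of another abundant group, against 1.36 in that group. Of 17 families with at least 3 groups, 14 had a median log2 ratio within the range of 10000 random lists matched on abundance. The family of GAGGTAG was within that range as reported and stood apart with the GC trend removed. In the family of GAGGTAG, 8 of 9 groups were higher in low RFI as scaled here and 5 of 9 with TMM scaling, and its share of the grouped reads was 16.5% in low RFI and 9.50% in high RFI. Its members TGAGGTAGTAGGTTGTGTGGTT and TGAGGTAGTAGTTTGTACAGTT had log2 ratios of 1.49 and 0.56, which were 0.84 and -0.09 with TMM scaling, and 1.60 and 1.45 with the GC trend removed. The family of GTAAACA was split, with 3 of 6 groups higher in low RFI and 2 of 6 with TMM scaling. In it TGTAAACATCCCCGACTGGAAGC was 2.13-fold higher in low RFI, with a log2 ratio of 1.09 that was 0.44 and no longer past 1.5-fold with TMM scaling, and TGTAAACATCCTTGACTGGAAGC, which had a log2 ratio of -0.65, was 1.57-fold higher in high RFI. The latter was -0.40 and no longer past 1.5-fold with the GC trend removed. The family of CAGTGCA ran from a log2 ratio of -0.64 to 1.96, or from -0.16 to 2.44 with the GC trend removed, between TCAGTGCACTACAGAACTTTGT and TCAGTGCATCACAGAACTTTGT.

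The families of CCCCAGT and GCTCCGT stood apart as lower in low RFI, at percentiles 0.365 and 1.30 of the matched lists, with median log2 ratios of -2.45 and -1.42. All 5 groups of each were higher in high RFI. TMM scaling could not change this, since it lowers every log2 ratio. In the first, 3 groups were the single-base forms G9A, G9C and G9T of GCCCCAGTGGCCTAATGGA, counted from its 5 prime end, so its members were not independent. The matched lists drew each member separately, so the percentile of this family counts related forms as separate members. In the second, 1 group held 674 of the 883 reads in low RFI and 2467 of the 3316 in high RFI. The family of CGAATCC stood apart as higher in low RFI, at percentile 97.9 with a median of 1.90, but no longer did with 1 mismatch allowed or with the GC trend removed.

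The last question was whether the ends of the small RNAs differed. In the group of TGAGATGAAGCACTGTAGCT, 59.5% of reads in low RFI (59.4 to 59.7) and 61.0% in high RFI (60.9 to 61.1) were identical to that sequence. The mean insert length was shorter in high RFI in 128 of 163 groups, with a median difference of 0.046 nt, and in all 10 of the most abundant groups. The difference was 0.62 nt in CTGACCTATGAATTGACAGC, where 38.6% of reads in low RFI and 59.4% in high RFI were identical to the sequence. It was 0.18 nt in TACAGTACTGTGATAACTGAAG, where the identical share went the other way, at 41.9% in low RFI and 32.4% in high RFI. It was 0.15 nt in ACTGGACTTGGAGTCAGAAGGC and 0.11 nt in TGGAGTGTGACAATGGTGTTT. Of the 10 most abundant groups, the identical share was higher in high RFI in 6 and higher in low RFI in 4.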

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

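All of the tests in this part were chosen after the results were seen. The forms of 2 of them, those of size selection and of amplification for the most abundant group, were also changed once their first outcome was known, and both forms are given.

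Reads with no adapter lie outside the groups compared, and the 6 most abundant such tags are given, a number chosen after the data were examined. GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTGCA had 402014 reads in low RFI and 1106906 in high RFI, 2.38-fold more per read sequenced (2.37 to 2.39). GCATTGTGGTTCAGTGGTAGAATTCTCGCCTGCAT had 149749 and 383138 reads, 2.21-fold more in high RFI (2.20 to 2.22), and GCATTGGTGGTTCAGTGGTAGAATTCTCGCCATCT had 59419 and 146278, 2.13-fold more (2.11 to 2.15). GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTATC, with 145061 reads in low RFI and 176923 in high RFI, differed by 1.05-fold (1.05 to 1.06). The tags that start with GCATTGGTGG differ only in their last bases, so they may be end variants of 1 RNA. Those that end in ATCT and ATC may hold the first bases of the adapter. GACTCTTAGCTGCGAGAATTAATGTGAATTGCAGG had 248640 reads in low RFI and 49472 in high RFI, 5.82-fold more in low RFI (5.76 to 5.87). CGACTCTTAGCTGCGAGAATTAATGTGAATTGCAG had 187330 and 31279 reads, 6.93-fold more in low RFI (6.85 to 7.02). Any counted tag lies above the limit that a count of 0 allows, so that limit does not set these tags apart from others.

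The most abundant group, TGAGATGAAGCACTGTAGCT, took a larger share in high RFI, and the tables argue against GC content as the whole cause. Its log2 ratio was -0.97 as reported, and it was -0.83 once the trend with GC was removed. The other scalings tried shifted every log2 ratio by -0.08 to -0.65, so they could only widen the difference. They cannot decide whether scaling is a cause. Size selection was first tested against the sum of the other groups at each insert length, which left -0.25 at 20 nt, -1.05 at 21 nt and -1.35 at 22 nt, and then against the median other group, which left -1.34, -1.02 and -1.74, so that it is argued against at 21 and 22 nt (-1.02 and -1.35, the weaker values) and open at 20 nt, the length of the sequence itself. Uneven amplification was first tested by the share of end variants higher in high RFI, 24 of 28 or 85.7%, under the bound of 90%, and then by the median log2 ratio of the other 27 variants, -0.93, which leaves it open. A difference between the RFI lines also stays open and untested, since each line is 1 library.

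Inserts of the same group were shorter in high RFI in 128 of 163 groups. Size selection may contribute, since the log2 ratio rose with length between groups by 0.15 per nt (bootstrap interval 0.014 to 0.31), close to the median of 0.11 per nt within groups (0.093 to 0.13). The relation with length was weak, with a Spearman correlation of 0.12 over the 163 groups, against 0.50 with GC content. Groups are not independent, so the bootstrap interval is a description only. A or T extensions were less frequent in high RFI in 87 of 163 groups, with a median difference of 0.060 percentage points. They did not account for the whole pattern, since 113 of 163 groups were still shorter once all inserts longer than the main sequence, whatever their added bases, were left out, although the median difference, over inserts with the same 5 prime end, went from 0.043 to 0.020 nt. A difference between the RFI lines was not tested.

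The 36 groups nearly confined to 1 library were picked for their counts, so no test of counting noise was made on them. Of the 24 in low RFI, 15 had no read in high RFI, and of the 12 in high RFI, 2 had none in low RFI. RNA of another source in 1 library may account for them, and the median share of reads in longer tags, 10.2% for those in low RFI and 13.15% for those in high RFI against 2.23% for the other groups, does not exclude it. Some sequences confined to low RFI resembled bacterial ribosomal RNA on inspection, which was not tested. With no reference sequences used here, this and a difference between the lines cannot be told apart.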

How the results depend on the processing

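Most alternatives were planned before the data were examined; those on longer tags, read errors, groups nearly confined to 1 library, GC content and scaling to inserts of 18 to 26 nt were chosen after. No paired analysis was possible because each line is 1 library and no test was made, and for the same reason no library could be left out and no other splits of the samples exist. Everything that needs miRNA names or hairpins was not run, nor was the end usage of identical inserts only, which is fixed at its whole. For changes of value the cause was not tested, except that counts with another minimum follow from the number of groups counted. Groups at least 1.5-fold higher in low RFI, 254 as reported, numbered 134 with TMM and with DESeq2 scaling. With at least 20 reads the groups higher and lower numbered 534 and 235, with no minimum 102933 and 101110, and with at least 1000 reads 82 and 37. With no limit on longer tags they numbered 1131 and 513; the groups lower numbered 65 with at most 5% in longer tags and 213 with possible read errors kept, against 100 as reported. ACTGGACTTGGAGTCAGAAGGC reversed to -0.030 with TMM and -0.033 with DESeq2 scaling, and CATTGCACTTGTCTCGGTCTGA, 0.64 as reported, to -0.013 and -0.015. Of the 44 named groups, 38 kept their sign under each alternative. The other scalings lower every log2 ratio, so groups already below 0 could not change sign under them. Those named for the highest ratios lay too far above 0 to do so. The number that kept their sign thus follows in part from how groups were picked. The other 6 changed sign in 14 of 528 alternative values, all under other scalings. These were the 2 groups above, past 1.5-fold as reported, and 4 that were not, with TMM values of -0.23 for TGAGGTAGTAGATTGTATAGTT, -0.53 for TCAGTGCATGACAGAACTTGG, -0.09 for TGAGGTAGTAGTTTGTACAGTT and -0.15 for TGTAAACATCCTACACTCTCAGC. Of the 528 values, 307 stayed within the counting interval.

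Shares follow for low and high RFI. The share of the most abundant group was 16.2% and 30.6% with identical inserts only, 16.2% and 31.8% with the 5 prime end exact, 15.7% and 30.7% with 1 mismatch, and 15.7% and 30.8% with shared reads divided. The share in defined-length groups was 22.5% and 29.2% with identical inserts only, 37.7% and 45.9% with the 5 prime end exact, 40.1% and 48.9% with 1 mismatch, 39.2% and 47.8% with shared reads divided, 41.8% and 49.9% with tags read at least 2 times, 39.0% and 47.6% with 10 nt of adapter, and 79.4% and 83.9% of inserts of 18 to 26 nt. The 22 nt share was 16.03% and 17.4% with tags read at least 2 times, and of inserts of 18 to 26 nt it was 31.1% and 29.7%, the opposite order. Identical reads in the most abundant group were 59.9% and 61.2% with the 5 prime end exact, and 58.2% and 59.6% with 1 mismatch. Depth limits groups near 100 reads, and no group has a replicate.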

Other observations

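A scan chosen after the data were examined took 350 pairs of groups that differed by 1 substitution, and compared the share of the less abundant form in each library. The less abundant forms included groups set aside as possible read errors. Pairs in which the less abundant form had fewer than 10 reads in a library were then passed over, and their number is not given. In 2 of the pairs left, the share differed at least 3-fold with intervals that did not overlap. The form G8A of AGAATCTGGATGAACTTTTTGG, with positions counted from the 5 prime end, was 1.59% of the pair in low RFI (0.98 to 2.41) and 14.3% in high RFI (13.1 to 15.5). The form G13A of TCGGACACGACTGAGCAACTGA was 8.54% in low RFI (5.36 to 12.8) and 44.6% in high RFI (38.9 to 50.4). The less abundant forms had 21 reads each in low RFI, and 481 and 136 reads in high RFI. Each library pooled 13 animals, whose genotypes were not analysed here.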
